A study of Mus musculus with 5 samples.

How the data were processed

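The series measured nuclear RNA and open chromatin in the same nuclei (10x Multiome) of mouse exTh17 cells, which are CD4 T cells that once expressed Il17a. Per the labels, CD4 cells of mice with an Il17a-Cre tdTomato fate reporter were transferred into Rag2-deficient mice, and arthritis was induced with 20 mg of mannan. Per the labels' protocols, cells were taken from joints of 12-week-old mice, stimulated with PMA and ionomycin, and sorted as tdTomato positive and negative in an IL-17A capture assay. The labels list 1 RNA sample and 4 ATAC samples, all of exTh17 cells, with no Th17 or other control group.

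The deposited matrix holds UMI counts of 32285 genes and counts at 105923 peaks, and a deposited fragment list gives each transposed fragment. Per the labels' protocols, reads were processed with cellranger-arc 2.0.1 and aggregated. Per the file headers, the reference was the mm10 package supplied with that software. Per the submitters' processing notes, nuclei were filtered in Signac 1.6.0 with EnsDb.Mmusculus v79, but the text of that filter breaks off before its values, so the thresholds used by the authors are not given in the sources used here.

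All barcodes carried the same suffix, so nuclei could not be assigned to the 4 ATAC samples, and the data formed 1 library. No replicates could be compared. The tests between libraries that had been planned were therefore not run, and no p-values, standard errors or counts of genes past a test are given. Values instead carry exact 95% Poisson intervals for counts and ratios of counts, and exact 95% binomial (Clopper-Pearson) intervals for shares. These intervals cover counting error only, not variation between mice or libraries. The Poisson intervals treat UMIs and fragments as independent, although 1 nucleus can give many of them. They leave out variation between nuclei and can therefore be too narrow. A group with 0 counts was set to a floor of 3 counts, and to a ratio of 1 where that floor would have turned the direction.

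Nuclei were kept with 500 to 25000 UMIs, 1000 to 100000 peak counts and at most 20% mitochondrial UMIs. Of the barcodes, 175 had too few UMIs, 422 had too few peak counts, and 3 each exceeded the upper UMI limit, the upper peak limit and the mitochondrial limit. Some failed on several criteria, and 592 barcodes were left out in all. Scrublet (expected rate 0.06) called 0 doublets among the remaining 8703 nuclei at its threshold of 0.577, so it removed none and was counted as not having worked. Nuclei with 75 or more places where at least 3 fragments overlapped, 789 of 8703 (9.07%), were treated as multiplets in an alternative. Peak counts were converted to fragments by dividing by 2 and rounding up, because 84.0% of them were even numbers, as counts of both fragment ends would be. This was checked against the fragment list at 200 peaks, where the median ratio was 1 and the 5th percentile 0.987.

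Counts were scaled to 10000 per nucleus and logged, and the 2000 most variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 0.5 with scanpy 1.11.5. Genes of the fixed lists, mitochondrial genes, ribosomal protein genes and T cell receptor segments were left out of the clustering. Chromatin was not used for it. A cluster was called T-like when at least 3 T cell markers were detected, their median level reached at least 50% of that in all nuclei and no other type's marker was among its leading 10 genes. Markers of 15 cell types were used.

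Each T-like cluster was compared with all other T-like nuclei on UMIs summed per group, scaled to the group total (CPM). A large cluster weighs heavily in such a pool, so its high level can make the other clusters appear lower. Clusters 1 and 2 are the largest, and no alternative left either of them out of the pool. T-like nuclei with at least 1 UMI of Il17a or Il17f and none of Ifng (Il17-only) were compared with those that had an Ifng UMI and none of Il17a or Il17f (Ifng-only). That makes 7 comparisons. Fixed gene lists, 14 in number and holding 197 genes of which 195 were found, covered the Th17, Th1, Th2 and Tfh programmes, inflammatory cytokines and chemokines, Treg and Tr1 genes, naive and central memory genes, tissue residency genes, inhibitory receptors and exhaustion genes, immediate early and activation genes, interferon response genes, glycolysis and hypoxia genes, sterol synthesis genes and cell cycle genes. A list's median log2 fold was taken over members with at least 20 UMIs, with an interval from 2000 Poisson draws. It was placed among 10000 random lists of the same size matched on mean expression. This percentile describes the library and is not a test.

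Genes were named by rule. From each list came up to 4 genes with at least 20 UMIs whose intervals in the compared groups did not overlap, taken by size of fold. To these were added the 10 genes of largest and the 10 of smallest fold among genes of at least 50 CPM in either group that had not been used for the clustering. Clusters were made from the same RNA, so genes used for the clustering serve only to identify a cluster. Exceptions are the counts of gained genes and the start-site check of Hspa1a and Hspa1b. Some genes and motifs that met these rules are not reported here. The Il17-only and Ifng-only classes do not depend on the clustering. The filters, clustering settings, lists, cell type markers, motif sequences, classes and naming rule were chosen before the data were examined. The T-like level rule, the ranking of peaks without a test and the overlap definition of multiplets were set after the data had been seen.

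Start-site fragments are the fragments in peaks within 1 kb of a gene's start sites, from GENCODE mouse release M21. This annotation is close to that in the authors' reference package without being the same, and 95.4% of 21612 protein-coding gene starts in the deposited gene table lay within 1 kb of it. Peaks with at least 100 fragments were ranked by the bound of their interval nearest to no difference. The leading 1000 in each direction were searched for 20 consensus motifs, against the opposite set and against tested peaks matched on GC content and mean count (mean of 200 draws). Intervals of motif ratios are 95% normal approximations on the log scale. They treat peaks as independent units, which peaks are not. Coordinates are in mm10, counted from 1. Peaks within 100 kb of 10 cytokine and regulator genes that held at least 100 fragments in the comparison were also summed.

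The kept nuclei had medians of 2013 UMIs, 1253 genes and 12331 fragments, a median mitochondrial share of 0.253% and a start-site enrichment of 9.11. Totals were 20630382 UMIs in the matrix and 115558602 fragments, of which 93.8% lay in matrix barcodes. The median log2 fold of the 9894 genes at 5 CPM or more was -0.15 for cluster 4, -0.17 for cluster 5 and -0.10 for cluster 7, and folds of those clusters are to be read against these shifts. Scaling by trimmed means or by medians of ratios shifted each comparison by at most 0.09 on the log2 scale in either direction.

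The calculation was tested on simulated data drawn from the real means and totals over 12891 genes, with 200 genes changed 2-fold. Intervals held the true value for 95.8%, 95.6%, 95.9%, 96.1%, 96.8% and 97.2% of genes for clusters 1, 2, 3, 4, 5 and 7. Simulated counts were Poisson draws, the model behind the intervals, without variation between nuclei. This coverage therefore checks the calculation only, not how well the intervals hold for the real nuclei. Changed genes, all of at least 50 CPM, were recovered at 100% for clusters 1 to 5 and 88% for cluster 7. Recovery at lower levels was not examined. A list given a true median of 0.5 came out at 0.51, 0.52, 0.47, 0.34, 0.55 and 0.61. For 85582 simulated peaks with 200 changed 4-fold, 97%, 97.5%, 91.5%, 83.5%, 72% and 49.5% of the changed peaks were among the leading 200. Peak rankings for clusters 5 and 7 are therefore the least complete.

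Alternatives covered the UMI minimum, doublet scores, multiplets, scaling, the low count filter, class definitions, thinning to 1000 UMIs, the motif background, the start-site window, the clustering, comparisons without cluster 7 and the cytokine classes within cluster 1 or cluster 3 alone. Software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9, with seed 0.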

Results

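Nuclear RNA and open chromatin were measured together in exTh17 cells from arthritic mouse joints. The cells had been stimulated with PMA and ionomycin and were sorted as Il17a fate reporter positive and negative for captured IL-17A. The labels give 1 RNA and 4 ATAC samples of this cell type. After filtering, 8703 nuclei remained and 592 barcodes were left out, with 19505874 UMIs in all. From the 5th to the 95th percentile, nuclei held 931 to 4362 UMIs and 1628 to 26066 fragments. The series set out to describe how heterogeneous these joint cells are and which regulators go with their signature genes. No replicates and no comparison group were present, so all values describe 1 library.

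RNA of the T cell and sort genes was present in 8547 nuclei called T-like. Cd4 UMIs were found in 34.5% of them (33.5 to 35.5%) and Cd3e UMIs in 23.3%, against 10.3% and 10.9% of the 156 nuclei of the remaining cluster. Tnfsf11, which encodes the osteoclast differentiation factor RANKL, had UMIs in 44.6% of T-like nuclei (43.5 to 45.7%) at 579 CPM, against 19.9% and 160 CPM (128 to 197) in the other nuclei. Il23r, the receptor chain for IL-23, was found in 36.0%, against 9.62%. Median depths were 2009 UMIs in T-like and 2582 in the other nuclei.

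Il17a UMIs occurred in 7.09% of T-like nuclei (6.55 to 7.65%) at 47.1 CPM, although the sort had selected cells without captured IL-17A protein. The share was 2.56% (0.703 to 6.43%) in the other nuclei, at 11.1 CPM. Il17f occurred in 7.17% of T-like nuclei at 52.6 CPM, against 14.9 CPM in the others. Ifng, the signature Th1 cytokine, occurred in 3.00% (2.64 to 3.38%) at 17.6 CPM, against 0 of 156 other nuclei, which allows a share of nuclei with a UMI of up to 1.92% by the floor of 3 counts (exact upper bound 2.34%). Tbx21, the Th1 master regulator, was found in 6.53% of T-like nuclei, against 1.28% (0.156 to 4.55%) of the others. Csf2 (GM-CSF) was found in 9.80% of T-like nuclei at 75.3 CPM, against 24.2 CPM (12.9 to 41.3).

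Ccr6, a chemokine receptor of Th17 cells, was found in 6.12% of T-like nuclei against 1.92% of the others. Il22 was found in 3.03% against 1.28% (0.156 to 4.55%), intervals that overlap. Foxp3, the regulatory T cell factor, was found in 1.56% against 0 of 156. Il4 had 9 UMIs in all (0.0936% of nuclei). Tnf (9.51% against 30.8%) and Il10 (0.433% against 8.33%) were more frequent in the other nuclei, which also carried macrophage transcripts and are thus no background for these genes. When each nucleus was thinned to 1000 UMIs, the shares were 3.87% for Il17a, 3.92% for Il17f, 1.53% for Ifng and 31.1% for Tnfsf11.

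Few nuclei held RNA of both cytokine types. Il17a or Il17f UMIs were found in 1104 T-like nuclei and Ifng UMIs in 256. Both were found in 19 nuclei (0.222%, 0.134 to 0.347%), where the product of the shares gives 33.1 nuclei. Without multiplets the numbers were 15 and 26.3. Neither cytokine was detected in 7206 nuclei.

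RNA clustering gave 7 clusters, of which 6 were T-like. Cluster 1 held 2817 nuclei (32.4%), cluster 2 held 2800 (32.2%), cluster 3 held 1669 (19.2%), cluster 4 held 734 (8.43%), cluster 5 held 408 (4.69%) and cluster 7 held 119 (1.37%). Among the genes that built the clusters, Nlgn1, Grik2 and Penk led cluster 1, the interferon-induced Ifit1bl1 and Ifi208 led cluster 2, and Pik3ap1 and Cd200r1 led cluster 3. Heat shock genes led cluster 4, with Hspa1a at 6272 CPM. Gm13448 and Dnah7a led cluster 5, and Ky and Klrg1 led cluster 7.

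Cluster 6, with 156 nuclei (1.79%), met no naming rule. Its T marker level was 21.1% of that in all nuclei. Fibroblast transcripts were high in it, with Col1a1 at 1189 CPM against 3.85 in T-like nuclei, Col3a1 at 1905 against 3.32 and Dcn at 2146 against 18.9. Transcripts of macrophages (Lyz2, 323 CPM), antigen-presenting cells (Cd74, 1440 CPM), neutrophils (S100a8, 158 CPM) and endothelium (Flt1, 242 CPM) were also present. Cluster 6 was left out of the comparisons.

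Cytokine RNA was unevenly spread over the T-like clusters. Tnfsf11 UMIs were found in 72.3% of cluster 1 nuclei and 24.9% of cluster 2 nuclei. Ifng was found in 5.99% of cluster 3 and 5.18% of cluster 4, against 2.31% of cluster 1 and 1.54% of cluster 2. Il17a or Il17f was found in 18.2% of cluster 1, 16.4% of cluster 5 and 12.3% of cluster 4, but in 7.37% of cluster 3. Median depth ranged from 1726 UMIs in cluster 3 to 2338 in cluster 1, so levels in CPM are the depth-scaled form.

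**Figure D1:**
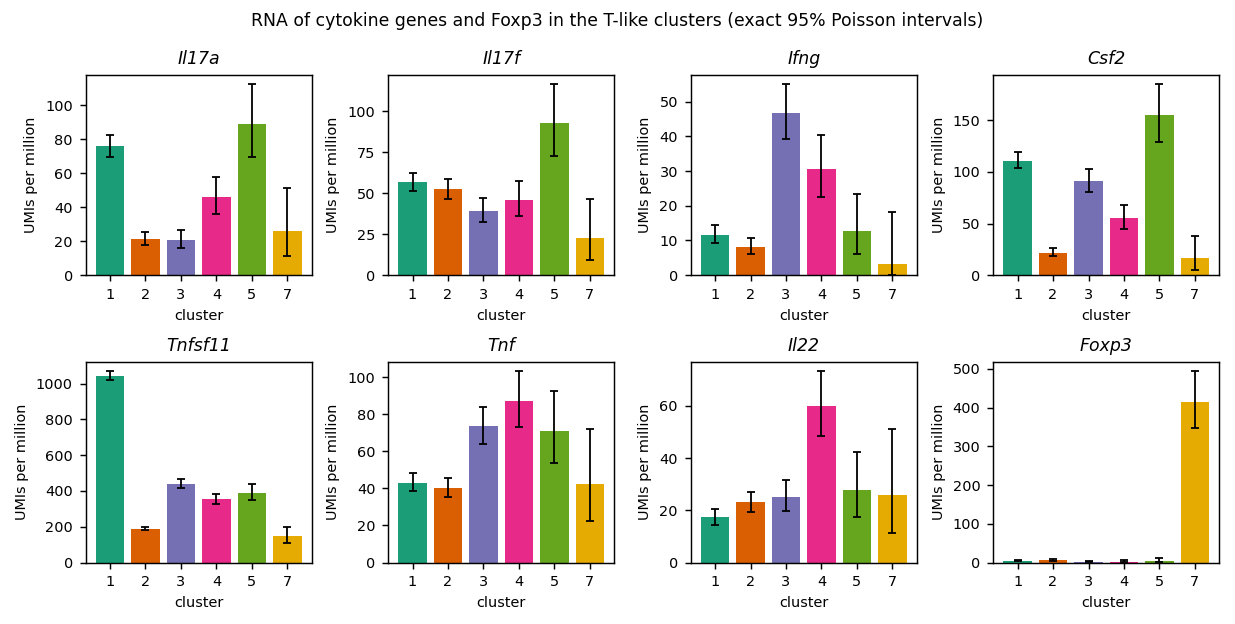
RNA levels in CPM (vertical axes, from 0) of 7 cytokine genes and Foxp3 in each T-like cluster (horizontal axes), with exact 95% Poisson intervals as bars. Tnfsf11 reached 1044 CPM in cluster 1, Ifng 46.7 in cluster 3 and Foxp3 415 in cluster 7.

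Cluster 1 against the other T-like nuclei asks what marks the largest group. Its nuclei were rich in Tnfsf11, at 1044 against 289 CPM, a log2 fold of 1.85 (1.79 to 1.91, 7599 and 3379 UMIs). Il17a was also higher, at 75.7 against 29.3 CPM (log2 fold 1.37, 1.17 to 1.57), as were Csf2 (1.06) and Ccl20 (1.18), the ligand of Ccr6. Most naive and central memory genes and most interferon response genes were lower.

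Among the genes of largest fold were Ccn4, a matricellular protein (log2 fold 2.25, 1.97 to 2.54), the tetraspanin Cd81 (2.12), the receptor tyrosine kinase Axl (2.02), the chemokine receptors Ccr7 (1.89) and Ccr4 (1.38), and the inhibitory receptor Lag3 (1.65). Of the inhibitory receptors and exhaustion genes, 7 of 8 members were higher, including Pdcd1 (1.05), Tox (1.04) and Btla (0.79), with a list median of 0.30 at percentile 99.9 of the random lists. Of the immediate early and activation genes 15 were higher and 7 lower (median 0.42, percentile 100), with Rel at 1.05, Junb at 1.02 and Nr4a2 at 0.89, while Jun was lower (-0.90). The Th17 programme had 12 members higher and 4 lower (median 0.14, percentile 97.0). Its member Il22 was lower (-0.74), and Rora was higher by 0.30 at 3064 CPM. Il13 (1.80) and Ccl1 (1.59), a ligand of Ccr8, were higher on small counts of 104 and 88 UMIs.

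Naive and central memory genes had the lowest list median, -1.22 (-1.33 to -1.02, 7 of 10 lower), although their summed UMIs differed little (-0.12). Klf2, a factor of quiescent T cells, was lower (-1.93), and Lef1 was lower (-1.38). Ccr7 was among the 3 members that were higher. Interferon response genes were lower in 14 of 15 (median -0.68, percentile 0), including Ifit3 (-1.76) and Oas2 (-1.56). The pool includes cluster 2, where these genes were high. The member Ifit1 was at 907 CPM in cluster 1, 1982 in cluster 2, and 697, 615, 796 and 1583 in clusters 3, 4, 5 and 7. Gbp2 was at 231 CPM in cluster 1, 752 in cluster 2, and 189, 126, 265 and 337 in clusters 3, 4, 5 and 7. The Th1 programme had 11 of 15 members lower (median -0.52), including Cxcr3 (-1.84) and Klrd1 (-1.43), although its summed UMIs were higher by 0.37. Itgae, which encodes the CD103 integrin chain, was lower too (-1.91, and -1.69 with cluster 7 left out).

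Chromatin around Tnfsf11 was more open in cluster 1. Fragments were higher at 27 of 28 peaks that lay within 100 kb and held at least 100 fragments, with a summed log2 fold of 0.71 (0.67 to 0.75). The largest fold among the 28 peaks, 2.43 (1.90 to 2.99), was at chromosome 14, 78276589 to 78277210, which lies 30833 bp from the start site. Start-site fragments summed to a log2 fold of 0.09, from peaks that moved in opposite directions. The peak over the start was at 0.48 (0.34 to 0.62) and its neighbour at -0.42 (-0.58 to -0.25). The Il17a start site was more open (1.09), while that of Ccr7 was less open (-0.50) despite higher RNA. The NR4A motif occurred in 13.5% of the 1000 leading more open peaks and 4.5% of the less open ones, a ratio of 3.00 (2.17 to 4.16), and 2.44 against matched peaks. AP-1 sites were found in 51.2% against 23.7%. The T-box motif was more frequent in less open peaks, by a ratio of 1.78 (1.20 to 2.64).

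**Figure D2:**
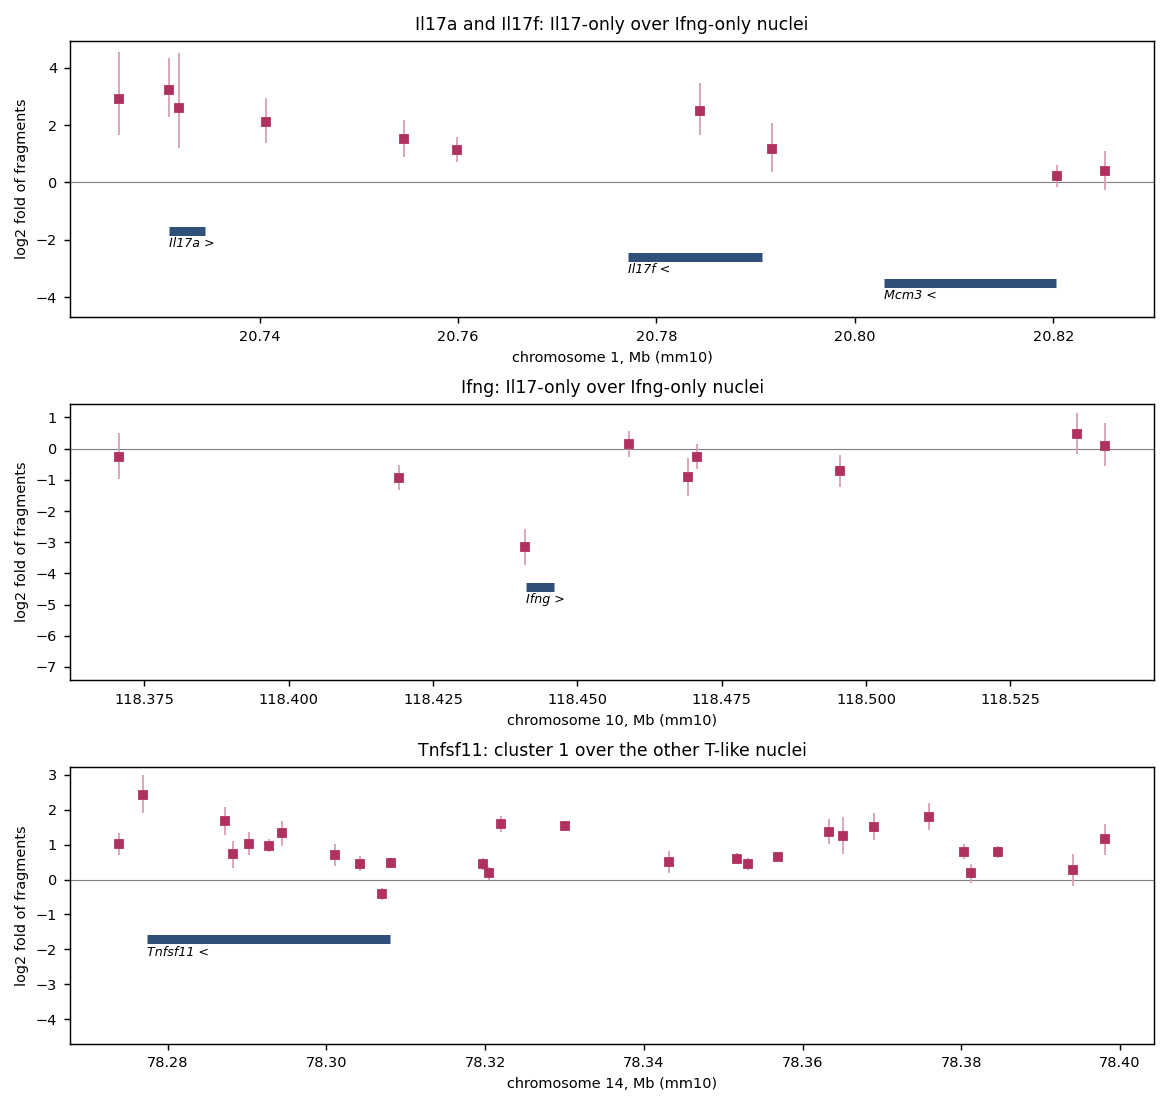
Log2 fold of fragments (vertical axes) at each peak of at least 100 fragments within the plotted window (squares, with 95% Poisson intervals as lines) along mm10 chromosomes in Mb, with gene bodies below and arrowheads for strand. At the Il17a and Il17f genes 10 of 10 peaks were higher in Il17-only nuclei, near Ifng 6 of 9 were lower, and around Tnfsf11 27 of 28 were higher in cluster 1.

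Cluster 2 against the other T-like nuclei shows the interferon response genes. All 15 measured members were higher, with a median log2 fold of 1.25 (1.22 to 1.29, percentile 100). Ifit3 stood at 230 against 50.4 CPM, a log2 fold of 2.19 (2.06 to 2.33), Oasl2 at 1.90, Ifit2 at 1.88, and the GTPase gene Gbp2 at 752 against 213 CPM (1.82). All 15 start sites held more fragments as well, by a median of 0.39, with Ifit3 at 1.64. Activation genes and several cytokines were lower in the same nuclei.

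Immediate early and activation genes were lower in 22 of 22 (median -1.23, summed UMIs -0.79, percentile 0), among them Nr4a2 (-2.59), Egr3 (-2.29) and Fos (-1.79). All cells had been stimulated and no unstimulated cells were measured. Activation and cytokine differences between clusters, also those of cluster 1, thus cannot be told apart from unequal response to the stimulation. Tnfsf11 was at 190 against 759 CPM (log2 fold between -2.09 and -1.91), Csf2 at -2.20, Il13 at -3.49 on 6 UMIs and Il17a at -1.45, while Il17f (-0.01, -0.21 to 0.18) and Il22 (-0.13, -0.43 to 0.16) did not differ beyond counting error. The inflammatory cytokines and chemokines had 11 of 17 members lower (median -0.48). Inhibitory receptors and exhaustion genes were lower in 7 of 8 (median -1.12, summed UMIs -0.26), including Entpd1 (-2.35), Havcr2 (-2.13) and Tox (-1.37). Treg and Tr1 genes were lower in 10 of 10 (median -0.77), including Itgb8 (-3.81, and -2.65 with cluster 7 left out), an activator of latent TGF-beta, and Lag3 (-2.18). With cluster 7 left out the Treg and Tr1 median was -0.49, and the members Foxp3 (0.97) and Ikzf2 (0.15) were higher instead of lower. The Th2 programme was lower in 6 of 7 (median -0.61).

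Naive and central memory genes were higher in 7 of 10 (median 0.36, percentile 99.3), with Lef1 at 1.48, the egress receptor S1pr1 at 1.43 and Tcf7 at 1.36. Slamf6 (1.80) was higher as well. The Th1 programme was divided, with 9 of 15 members lower (median -0.32), Tbx21 at -1.66 and Nkg7 at -1.49, but Cxcr3 at 1.75 and Klrd1 at 1.68. Itgae was higher (1.04).

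The Tnfsf11 locus was less open at 27 of 28 peaks, with a summed log2 fold of -0.61 (-0.66 to -0.57). The Il17a start site was less open too (-0.66), although 12 of 21 peaks around Il17a were higher, with a summed log2 fold of 0.14 (0.09 to 0.18). TCF-LEF motifs were found in 14.2% of more open and 5.5% of less open peaks, and NR4A motifs in 4.1% and 12.1%. The IRF motif was 3.00 times as frequent in more open as in less open peaks (1.75 to 5.16), but this ratio was 1.31 against peaks matched on GC content and mean count.

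Cluster 3 was compared with the other T-like nuclei, from which it differed in Ifng RNA. Ifng was at 46.7 against 12.1 CPM, a log2 fold of 1.95 (1.62 to 2.27, 141 and 193 UMIs), and its start site was more open by 1.21. The IL-12 receptor chain Il12rb2 was higher (1.12, 0.96 to 1.27), with its start site at 1.02, and so was the cytotoxic granule gene Nkg7 (1.40). Il17a was lower, at 20.8 against 52.1 CPM (-1.32, -1.71 to -0.95), with its start site at -0.68. Still, more cluster 3 nuclei held Il17a or Il17f (7.37%) than Ifng (5.99%). Neither level was particular to cluster 3, with Ifng at 30.6 CPM in cluster 4 and Il17a at 21.5 CPM in cluster 2. Tbx21 was at 52.3 CPM in cluster 3 and 122 in cluster 4.

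The Th17 programme was lower in 12 of 16 (median -0.34, percentile 0), including Ccr6 (-1.26), the aryl hydrocarbon receptor Ahr (-0.68) and Il17f (-0.49). The Th1 programme as a list was balanced, with 8 members higher and 7 lower (median 0.00, summed UMIs -0.08). The higher Ifng, Nkg7, Il12rb2 and Fasl (0.60) thus did not extend to the list as a whole. Of 14 Th1 members with a start-site peak, 10 were more open there and 4 less open (median 0.13). Csf1 (1.38), a macrophage growth factor, and Tnf (0.63) were higher, and Xcl1 was higher on 10 UMIs (2.02, 0.67 to 3.32). The metalloprotease Adam8 (1.03), the amino acid transporter Slc7a5 (0.99), the glucose transporter Slc2a3 (0.81), Entpd1 (1.00), Havcr2 (0.93) and Cd44 (0.52) were also higher. Interferon response genes were lower in 15 of 15 (median -0.89, percentile 0), with Oasl2 at -1.33 and Gbp2 at -1.15. The pool includes cluster 2, where these genes were high. The member Ifit1 was at 697 CPM in cluster 3, 1982 in cluster 2, and 907, 615 and 796 in clusters 1, 4 and 5. Ccr7 (-1.93), Ccr4 (-1.75) and Tox (-1.61) were lower, and Tnfsf11 was lower by a log2 fold of -0.46. That pool includes cluster 1, and Tnfsf11 in cluster 3, at 440 CPM, lay between cluster 1 (1044) and cluster 2 (190). The Tfh programme (median -0.51, summed UMIs -0.15, 5 of 8 lower), the Th2 programme (-0.59), naive and central memory genes (-0.43) and Treg and Tr1 genes (-0.36) had lower medians.

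Of 28 peaks within 100 kb of Ifng, 23 were more open, with a summed log2 fold of 0.35 (0.30 to 0.41). The peak over the Ifng start, chromosome 10, 118440492 to 118441360, was at 1.44. T-box motifs, bound by the Tbx21 family, were found in 12.8% of more open and 3.4% of less open peaks, a ratio of 3.76 (2.61 to 5.44), and 2.99 against matched peaks. NF-kB motifs were more frequent in the less open peaks, by a ratio of 2.91 (2.18 to 3.88).

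Cluster 4 against the other T-like nuclei describes the heat shock group. Beyond the genes that built the cluster, the chaperone gene Dnajb4 (1.92) and the stress-induced zinc finger gene Zfand2a (2.22) were higher. Immediate early genes were high, with Jun at 405 against 87.9 CPM, a log2 fold of 2.20 (2.07 to 2.34), Dusp2 at 1.74 and Fosb at 1.71. Tbx21 was at 122 against 34.4 CPM (1.82, 1.58 to 2.06) and the IL-1 receptor gene Il1r1 at 662 against 221 CPM (1.58). The median gene had a log2 fold of -0.15 in this cluster.

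Immediate early and activation genes were higher in 20 of 22 (median 0.96, summed UMIs 0.56, percentile 100). Il21 (2.44, on 22 UMIs), Il22 (1.49) and Ahr (1.32) were the other large folds of the Th17 programme, whose median was 0.08 with 9 of 16 higher. Inflammatory cytokines and chemokines were higher in 11 of 17 (median 0.26, summed UMIs -0.04), with Csf1 at 1.39, Cd40lg at 1.18 and Tnf at 0.85, and with Tnfsf11 lower (-0.76). At 354 CPM, Tnfsf11 lay between cluster 1 (1044) and cluster 2 (190). Id3 (3.47) and Klf2 (1.78) were higher, while Ccr7 (-1.47) and the IL-7 receptor gene Il7r (-0.98) were lower.

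Interferon response genes were lower in 15 of 15 (median -1.10, percentile 0), including Oas2 (-2.35), Gbp2 (-1.69) and Irf7 (-1.55), and 14 of 15 start sites held fewer fragments (median -0.44). Glycolysis and hypoxia genes were lower in 10 of 15 (median -0.44), with Pgk1 at -0.98, Aldoa at -0.94 and Ldha at -0.91. Sterol synthesis genes were higher in 9 of 11 (median 0.34), with Hmgcs1 at 0.82. The Il17a locus was less open at 20 of 21 peaks (summed log2 fold -0.48, -0.57 to -0.39). NF-kB motifs were more frequent in more open peaks by a ratio of 2.62 (2.00 to 3.43). IRF motifs were more frequent in less open peaks by 2.48, and by 1.56 against matched peaks.

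Cluster 5 against the other T-like nuclei gave large folds of genes that were nearly silent elsewhere. The claudin gene Cldn11 was at 77.5 against 1.27 CPM, a log2 fold of 5.94 (5.22 to 6.70, 61 and 23 UMIs). Islr2 (5.15), Ankrd42 (4.31), Adam32 (3.58) and Cd59b (3.13) were also higher. Csf2 was at 155 against 71.9 CPM (1.11, 0.83 to 1.38), and Il17a at 88.9 against 45.3 CPM (0.97, 0.60 to 1.33), with Il17f at 0.87. The 122 Csf2 UMIs of cluster 5 came from 47 of 408 nuclei. That share, 11.5% (lower bound 8.59%), did not differ beyond counting error from the 9.80% of all T-like nuclei. It was below the 14.8% of cluster 1, so the higher Csf2 level was not a cluster-wide rise. By a fixed size rule, a log2 fold of at least 2 on at least 20 UMIs, 206 genes were gained. Clusters 1, 2, 3, 4 and 7 gained 69, 68, 3, 58 and 66. These counts include genes that built the clusters, and 20 UMIs is a higher CPM in a cluster of fewer total UMIs, so they are not on 1 scale. Of the 206 genes, 50% had an expressed gene ending within 20 kb upstream on their strand.

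The Th17 programme had 10 of 16 members higher (median 0.22, -0.10 to 0.31), although Il23r (-0.49) and Maf (-0.48) were lower. Immediate early and activation genes were higher in 19 of 22 (median 0.31), with Egr3 at 2.59 on 12 UMIs, Egr1 at 1.83 and Fosb at 0.86. Il5 (3.35, 19 UMIs), Il10 (2.84, 9 UMIs), Tox2 (1.16) and the IL-2 receptor chain Il2ra (0.79) were higher. Lower genes included Csf1 (-1.79), Atp8a1 (-1.73), Ccr7 (-1.08), the ubiquitin ligase Cblb (-0.94) and Tnfsf11 (-0.59). At 391 CPM, Tnfsf11 lay between cluster 1 (1044) and cluster 2 (190). Tissue residency genes were higher in 8 of 11 (median 0.22). Interferon response genes were lower in 14 of 15 (median -0.42), with Ifit2 at -1.18 but Oas2 at 1.47. Naive and central memory genes were lower in 8 of 10 (median -0.50). Treg and Tr1 genes were lower in 7 of 10 (median -0.46), although their summed UMIs were higher by 0.11.

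Start sites followed RNA least in this cluster, with 29 of 58 genes of at least 2-fold RNA difference moving in the same direction. CTCF motifs were 5.99 times as frequent in more open as in less open peaks, but 1.35 times against matched peaks. IRF motifs in less open peaks had ratios of 4.07 and 1.61.

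Cluster 7 against the other T-like nuclei showed a regulatory T cell gene set. Foxp3 was at 415 against 4.45 CPM, a log2 fold of 6.54 (6.13 to 6.96, 128 and 83 UMIs), and its start site was more open by 3.89. Ikzf2, which encodes Helios, was at 3630 against 66.9 CPM (5.76), the IL-33 receptor gene Il1rl1 at 791 against 12.9 CPM (5.94), and Itgb8 at 6.20. Treg and Tr1 genes were higher in 10 of 10 (median 1.52, 1.19 to 1.62, percentile 100). Multiplets made up 18.5% of these 119 nuclei, and without them Foxp3 was at 6.82. Some transcripts of other cell types were also higher here than in all T-like nuclei: Igkc at 38.9 against 1.74 CPM (12 of 33 UMIs), Cd74 at 237 against 51.6 and H2-Ab1 at 84.3 against 24.7.

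The Th2 programme was higher in 5 of 7 (median 1.30), with Gata3 at 1.30 and Pparg at 2.29 on 5 UMIs. Inhibitory receptors and exhaustion genes were higher in 7 of 8 (median 1.10), including Tigit (2.86), Tox (2.83) and Entpd1 (2.65). The granzyme gene Gzmb (5.36), the costimulatory receptor Cd27 (4.87), Itgae (3.31), the repair-associated growth factor Areg (1.81) and Icos (0.95) were higher. Il12rb2 was lower on 1 UMI (-4.75, -10.06 to -2.27), with its start site at -2.07. Cd40lg (-2.44), Csf2 (-2.23), Tnfsf11 (-1.97), Bach2 (-1.89), Cxcr6 (-1.49) and Il17f (-1.23) were lower. The Th17 programme median was -0.22 with 10 of 16 lower, although summed UMIs were higher by 0.14. The cell cycle genes Mcm3 (1.15), Mki67 (0.80) and Diaph3 (0.77) turned to -0.27, -0.28 and -0.79 once multiplets were left out. Nuclei that have copied their DNA can also reach the overlap limit, so this filter cannot tell multiplets from cycling nuclei.

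Chromatin at some cytokine loci was less open in cluster 7. Around Tnfsf11, 27 of 28 peaks were lower (summed log2 fold -1.29, -1.55 to -1.04), and around Il17a 17 of 21 (-0.82, -1.06 to -0.60). The Ifng start site was at -1.86. The Il10 locus (-0.04, -0.17 to 0.08) and the start sites of Tnf (0.04) and Lta (0.12) did not differ beyond counting error, and the Areg start site was more open (0.85, 0.39 to 1.28). NR4A motifs were more frequent in more open peaks by a ratio of 1.83, and 2.15 against matched peaks.

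**Figure D3:**
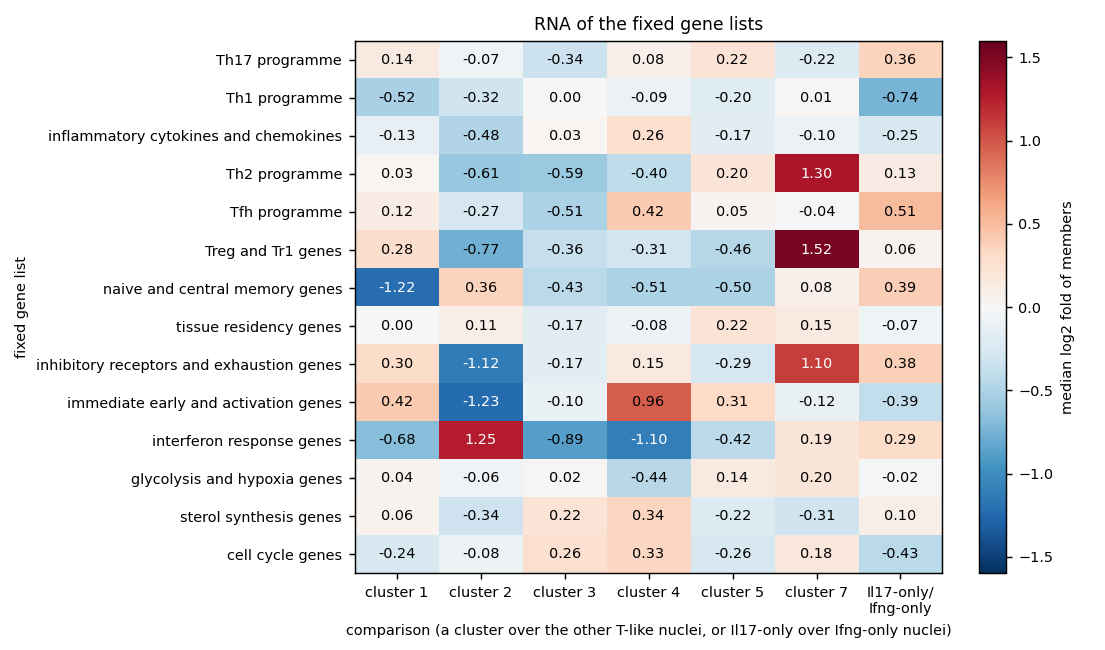
Median log2 fold of each fixed gene list (vertical axis) in each comparison (horizontal axis), as coloured and printed values. The interferon response genes ranged from 1.25 in cluster 2 to -1.10 in cluster 4, and the Treg and Tr1 genes reached 1.52 in cluster 7.

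Il17-only nuclei (1085) were compared with Ifng-only nuclei (237) to ask which genes and regions go with Il17 and with Ifng RNA. The classes also differed in cluster: 506 Il17-only and 59 Ifng-only nuclei lay in cluster 1, against 117 and 94 in cluster 3. Ccr6 had 170 UMIs (61.7 CPM) in Il17-only and 0 in Ifng-only nuclei, a log2 fold of 3.72 at the floor of 3 counts (lower bound 3.41). Il12rb2 was at 33.4 against 236 CPM (-2.82, -3.21 to -2.44), and Tbx21 at a log2 fold of -2.37 (-2.85 to -1.89). Csf2 was higher in the Ifng-only nuclei, at 59.2 against 234.0 CPM (-1.98, -2.31 to -1.65).

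Outside the genes that define the classes, the Th17 programme was higher in 9 of 14 (median 0.36, percentile 99.9), with Ahr at 0.99, Il1r1 at 0.90 and Il23r at 0.63. The actin-associated Palld (3.70), the myosin Myo3b (3.49), the splicing factor Rbfox1 (3.53), Ccr4 (1.55), Tox (1.52), Areg (1.46), Ccr7 (1.14) and Icos (0.80) were higher in Il17-only nuclei. The Th1 programme was lower in 10 of 14 (median -0.74, summed UMIs -0.15, percentile 0), with Nkg7 at -3.52. This median was -0.25 when members under 20 UMIs were kept. Csf1 (-2.31), Entpd1 (-2.33), Il1rl1 (-1.99), Klf2 (-1.72), Havcr2 (-1.44), Lta (-1.36) and the adhesion molecule Dscam (-4.80) were lower.

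Immediate early and activation genes were lower in 18 of 22 (median -0.39, summed UMIs -0.11), including Dusp2 (-1.26). Nr4a2 was lower as well (-0.96), but was at 0.87 where at least 2 UMIs made a class. Cell cycle genes were lower in 15 of 18 (median -0.43), with Mki67 at -1.15. Interferon response genes were higher in 14 of 15 (median 0.29), with Oasl2 at 0.82, and the Tfh programme was higher in 5 of 8 (median 0.51). Naive and central memory genes (median 0.39) and inhibitory receptors and exhaustion genes (0.38) had higher medians. A nucleus without a UMI of a cytokine may still transcribe it, so these classes are defined by detection. Within cluster 3 alone the immediate early and activation median was 0.06 and the interferon response median -0.20, so neither direction held there.

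The chromatin of these classes differed at the defining cytokine genes. The Il17a start site held 504 fragments in Il17-only and 13 in Ifng-only nuclei, a log2 fold of 3.06 (2.27 to 3.97), Il17f was at 2.48, and the Ifng start site was at -2.38 (-2.80 to -1.95). The peak over the Il17a start, chromosome 1, 20730427 to 20731369, was at 3.22, and the 10 peaks within 100 kb that held at least 100 fragments were all higher (summed log2 fold 1.40, 1.20 to 1.60). For 2 of them, at 0.21 (-0.16 to 0.59) and 0.38 (-0.26 to 1.09), the interval crossed 0. By the same fragment limit, 13 of 16 peaks around Tbx21 were lower (-0.31), and 17 of 19 around Csf2 (-0.38). The Il17a start site was at 2.06 within cluster 1 alone and 3.65 within cluster 3 alone, and that of Ifng at -2.16 and -1.99. An intronic Tbx21 peak, chromosome 11, 97103829 to 97104694, was at -2.27. The start sites of Ccr6 (1.52) and Il12rb2 (-2.22) moved with RNA.

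T-box motifs were found in 9.7% of the peaks less open in Il17-only nuclei and 2.4% of the more open ones, a ratio of 4.04 (2.61 to 6.26), and 2.43 against matched peaks.

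**Figure D4:**
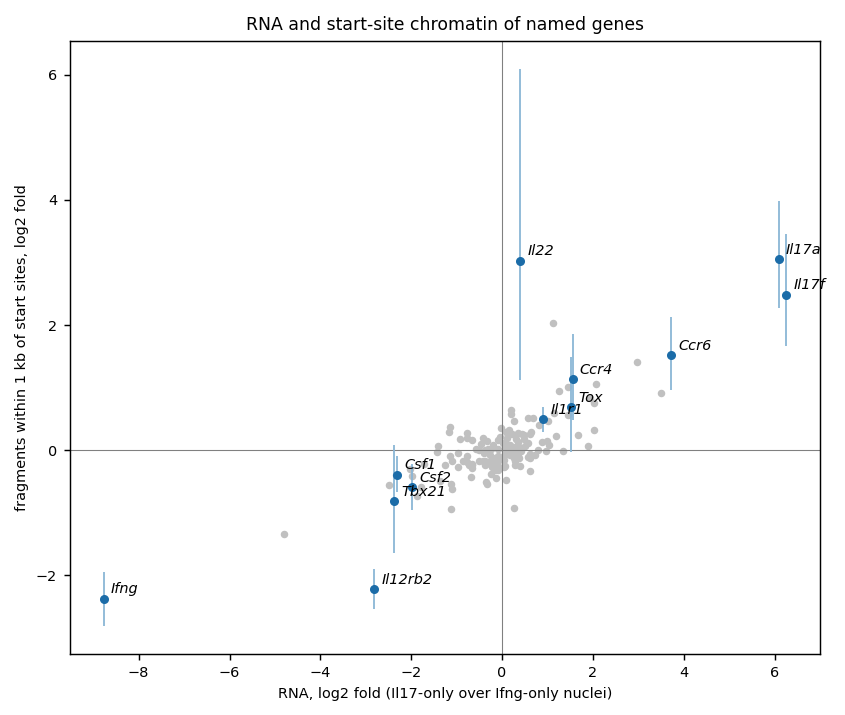
Log2 fold of RNA (horizontal axis) and of fragments within 1 kb of start sites (vertical axis) in Il17-only over Ifng-only nuclei for genes named by rule or in the fixed lists (grey points, at least 50 fragments each), with genes chosen after their values were seen in blue and 95% Poisson intervals of their fragments. Ccr6 lies at 3.72 and 1.52, and Il12rb2 at -2.82 and -2.22.

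RNA and start-site chromatin were compared across genes, which are not independent replicates. Over 3499 genes, Spearman's rho between RNA and start-site log2 folds was 0.333 for cluster 1, 0.356 for cluster 2, 0.272 for clusters 3 and 4, 0.138 for cluster 5 and 0.214 for cluster 7. Pearson's r was 0.432, 0.479, 0.412, 0.311, 0.141 and 0.322 in the same order. Between Il17-only and Ifng-only nuclei, rho was 0.186 and r was 0.326 over 3808 genes. Of genes with at least a 2-fold RNA difference, start sites moved in the same direction for 83.3% of 48 in cluster 1, 87.7% of 114 in cluster 2, 81.8% of 11 in cluster 3, 72.5% of 222 in cluster 4, 50% of 58 in cluster 5, 73.7% of 213 in cluster 7 and 91.0% of 67 between the cytokine classes.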

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

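The test of the gained genes' own start sites, the tests of the heat shock nuclei and the overlap definition of multiplets were chosen only after the result was seen.

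Signal from other cells was present outside the T-like nuclei used in the comparisons: cluster 6 made up 1.79% of kept nuclei, and Col1a1 stood at 1189 CPM in it, above the limit that a count of 0 allows. Free RNA from other cells brings no chromatin, yet fragments at the start sites of 5 fibroblast genes were higher than in T-like nuclei by a log2 fold of 1.42 (1.19 to 1.65), which argues against free RNA as the whole source. Doublets with T nuclei would keep a large part of the T-like level at T cell start sites. At 10 T cell genes these sites were at -2.25 (lower bound -2.52, upper bound -2.0), which argues against such doublets as the whole source. Nuclei of joint cells that passed the sort may be the source, and multiplets may form a part, since 19.2% of cluster 6 (30 of 156) were marked as such, the highest share of any cluster. The labels name no other cell type, so no biological explanation was tested.

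Overlapping fragments marked 789 kept nuclei as probable multiplets, a signal in the fragment list that the comparisons do not use.

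The 206 genes gained in cluster 5, which include genes that built the cluster, form the next pattern. RNA from the cluster 6 cells does not account for them, since their median log2 ratio of cluster 6 to cluster 5 was -2.74 (-2.78 to -2.51). Their own start sites were not more open, with a median log2 fold of 0.0231 (-0.07 to 0.04) over 128 genes. Read-through from an upstream neighbour may contribute and stays open, because 50% (43 to 57%) had an expressed same-strand gene ending within 20 kb upstream, against 10.3% of 1030 matched genes. That search also counts upstream genes that overlap the start and other gained genes.

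The heat shock nuclei of cluster 4 form the last pattern. For Hspa1a and Hspa1b, free RNA as the whole source is argued against by more open start sites, with a log2 fold of 1.29 (1.17 to 1.41). Both are leading genes that built the cluster, and other heat shock genes were not covered. Low RNA content is argued against by a median UMI count at 93.2% of that of the other T-like nuclei. Other damage stays open, as start-site enrichment was 7.82 in cluster 4, against 9.01 to 9.66 in the other T-like clusters. Warming or stimulation during preparation may account for the 8.59% of T-like nuclei in this cluster and cannot be told apart from a state of the joint, since no unprepared cells were measured.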

How the results depend on the processing

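Leaving out multiplets, leaving out cluster 7, the classes within cluster 1 or 3 alone and scaling by trimmed means (TMM) were added after the data had been seen. Over all alternatives 3380 values of 551 results were recomputed: 3075 stayed within their counting intervals (for numbers of nuclei and clusters, within a fixed ratio), 287 moved beyond them and 18 turned direction. Where a value moved, the cause was not tested, except that thinning lowers detection by its construction. Without multiplets, cluster 7 gave Mcm3 -0.27, Mki67 -0.28 and Diaph3 -0.79, all turned in direction. Nr4a2 between the cytokine classes turned to 0.87 with at least 2 UMIs per class (361 and 49 nuclei) and to 9.9e-05 after thinning (584 and 119 nuclei). With cluster 7 left out, Ikzf2 turned to 0.15 in cluster 2 and 0.36 in cluster 4, Foxp3 to 0.97 in cluster 2 and Il1rl1 to 0.59 in cluster 3, while Foxp3 in cluster 1 shrank to -0.18. Between the classes within cluster 3 alone (117 and 94 nuclei), the immediate early and activation median turned to 0.0627 and the interferon response median to -0.20. Oasl2 (-0.10), Gbp2 (-0.12), Ifit1 (-0.19), Ikzf2 (-0.18), Gpm6b (-0.81) and Nfkbid (0.19) turned there too, as did Ect2 (0.0306) within cluster 1 alone (506 and 59 nuclei), where the Il17a start site was at 2.06. The list medians below kept their direction. Without the top 10% of doublet scores, naive and central memory genes in cluster 1 were at -1.35, and interferon response genes at 1.35, -0.95 and -1.44 in clusters 2, 3 and 4. Without multiplets, naive genes in cluster 1 were at -1.33, interferon genes at 1.32 in cluster 2 and -1.33 in cluster 4, and Treg and Tr1 genes at 1.69 in cluster 7. Interferon genes in cluster 3 were at -0.94 with at least 1000 UMIs, -0.97 with TMM and -0.96 with medians of ratios (RLE). The Th1 programme between the classes was at -1.07 with at least 2 UMIs and -0.25 with no low count filter. Resolution 1.0 gave 14 clusters, against 6 at 0.3, 8 with the fixed lists kept and 7 from peak counts. In the last (adjusted Rand index 0.326), 50.2% of cluster 5 fell in a cluster of 3580 nuclei, and at most 35.1% of cluster 3 stayed together. At 0.3, 66.6% of cluster 3 fell in a cluster of 4059 nuclei, of which 68.7% were from cluster 1. Thinned shares were 3.87%, 3.92%, 1.53% and 31.1% for Il17a, Il17f, Ifng and Tnfsf11. Against matched peaks the motif ratios were 1.31 for IRF in cluster 2, 1.56 for IRF in cluster 4, 1.35 for CTCF and 1.61 for IRF in cluster 5, and 2.43 for T-box between the classes. With peaks within 10 kb, rho was 0.400, 0.430, 0.320, 0.177 and 0.274 for clusters 1, 2, 3, 5 and 7, and 0.253 between the classes. DESeq2, the edgeR test, leaving out each library, fits with and without a library block, and camera with a preset or an estimated correlation were not run, since they need several libraries. No paired analysis was possible because nuclei could not be assigned to samples. Depth limits rare transcripts most, such as Il4 with 9 UMIs.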

Other observations

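Several genes outside the sort panel were chosen here after their values were seen. Rora was detected in 95.1% of T-like nuclei at 2705 CPM, against 57.7% of cluster 6 nuclei, and Stat4, which acts downstream of IL-12 and IL-23, in 84.7% against 40.4%. Il18r1 was detected in 64.5% against 21.2%, Maf in 54.3% against 28.8%, Cd69 in 45.0% against 23.1% and Il1r1 in 32.2% against 30.1%. Il2 had 10 UMIs and Il3 had 1 despite stimulation, and Cd8a had 6.

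The cell cycle genes had medians of -0.24 in cluster 1 (14 of 18 lower, Hells -0.94), 0.26 in cluster 3 (14 of 18 higher) and 0.33 in cluster 4 (12 of 18 higher). Glycolysis and hypoxia genes were at 0.20 in cluster 7 (11 of 15 higher), where Bnip3 was at 1.98 and Egln3 at 1.80. Sterol synthesis genes were at -0.34 in cluster 2 (8 of 11 lower), with Idi1 at -1.15.

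The muscle gene Neb stood at 172 CPM in cluster 7 and Ttn at 441 CPM, against 9.02 and 161 CPM in T-like nuclei, while Myh4, Acta1 and Ckm had 0 UMIs there.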
